A study of Zea mays with 8 samples.

How the data were processed

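RAMOSA1 (RA1) is a maize zinc finger transcription factor that controls branching of the inflorescences, the male tassel and the female ear. Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was done on pooled tassel and ear primordia of 1 to 5 mm from plants carrying RA1 fused to an HA-FLAG tag or to the fluorescent protein YFP. Per the labels, each fusion carried its tag at the N-terminus, was built for expression in the native domain of RA1 and could complement ra1 mutants, and tassels were harvested about 4 weeks and ears 6 weeks after planting. An HA antibody was used for the first fusion and a GFP antibody for the second. The 8 samples are 4 ChIP libraries (tassel HA, tassel YFP, ear HA and ear YFP) and 4 input DNA libraries, so each combination of tissue and tag has 1 ChIP library. The 2 tags were not treated as replicates of one group, because transgene and antibody differ between them. Each input library is labelled with a tissue and a tag. The input libraries enter only through the authors' peak calling and their own values were not analysed here.

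Each ChIP library has a list of peaks and a list of summits, 1 summit per peak. The submitters' processing notes name CASAVA and MACS 1.4.0rc2, and the series text gives 1e-05 as the p-value limit for enrichment over input. The aligner settings, the read filters and whether each ChIP library was called against the input of its own label are not given in the sources used here. Sequence names in the deposited files carry the prefix of the maize B73 assembly AGPv2, and all coordinates are in that build. Files were read as BED, so 1 was added to each start for printing. The score that the authors deposited for each peak is taken as 10 times the negative log10 of the MACS p-value, since no score lies below 50, the value of that limit on this scale; no file header states it. Several of the strongest peaks share a score of exactly 3100 and so are tied, though a few lie above it. The summit signal that the authors deposited is the height of the fragment pileup in whole fragments, not scaled to depth. The total reads of each library are unknown here, so heights and peak numbers cannot be corrected for depth.

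Overlaps, regions and positions were computed on chromosomes 1 to 10 with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Peaks on the unplaced sequence (chr0) and the organelle genomes were set aside. A peak was shared when at least 1 bp overlapped. The share of the shorter list was compared with 1000 placements in which each of its peaks was moved by a random 50 to 500 kb on its own chromosome. This keeps the regional density of peaks but not the finer placement of mappable or accessible sequence. An excess over such placements is therefore not by itself a measure of agreement on RA1 sites. The smallest one-sided p that the placements can give is 0.001. The 6 pairs of lists were adjusted together with the Benjamini-Hochberg method. Pairs were also compared with lists limited to the 2875 peaks of highest score, the length of the shortest list. Regions are the merged peaks of all 4 lists, and a region found with both tags of a tissue holds a peak of each. Intervals on shares are exact 95% binomial (Clopper-Pearson) intervals. An overlap of intervals is not a test and does not show that shares are equal. Intervals, floors for a count of 0 (3 counts) and tests over peaks or regions cover counting error within these libraries only. Peaks are not replicates, so no p-value here measures variation between plants or repeated immunoprecipitations.

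Summit distances were compared with 1000 draws in which each summit was placed at random within its own peak. Chromosome counts were compared with 10000 multinomial draws in proportion to chromosome span, where the span ends at the last peak of any list. Counts over 10 deciles of the span were compared with 10000 draws of equal probability. Clusters of peaks were compared with the same local shifts. The regions named below were chosen by a fixed rule: the 10 regions of all 4 lists with the best worst-library rank of score, the 5 regions ranked likewise among those with both tassel peaks and no ear peak, the 5 among those with both ear peaks and no tassel peak, and the highest score of each list. Ties in rank were broken by the lower of the summit heights, a choice made after the ties were seen.

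The overlap test was checked on simulated lists of the real sizes. With 200 planted shared peaks in lists of 2875 and 4797, the excess over chance averaged 200.1 ± 1.39 (SD, 20 runs), and 20 of 20 runs passed p of 0.05. In lists of 6641 and 12840 it averaged 197.2 ± 6.71 (SD, 20 runs), and 20 of 20 runs passed. With no planted peaks, 0 of 20 runs passed at either size. The simulated peaks of a list had a single width and were placed evenly, and each run used 100 placements. The check therefore does not cover lists that are clustered or vary in width, as the real ones do. The comparisons, the rule for named regions and the following alternatives were set before the data were examined: overlap by 50% of each peak, summits within 300 or 100 bp, scores of at least 70 or 100, ranking by summit height, other placements, and removal of the top 1% by score or the widest 5%. The comparisons of summit heights between the tags, the limits on heights, the split of ear summit distances by tassel peaks, the test over deciles and the top 300 peaks were chosen after the data had been explored. The position of peaks relative to genes, gene lists and sequence motifs were planned but are not analysed here, because the gene table used is of a later assembly of B73 and coordinates were not converted between builds.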

Results

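RA1 occupancy was profiled in tassel and ear primordia with 2 tagged fusions of the protein, which gave 4 peak lists. The authors' lists held 2913 peaks for tassel HA, 4829 for tassel YFP, 6648 for ear HA and 12856 for ear YFP, of which 2875, 4797, 6641 and 12840 lay on chromosomes 1 to 10. Tassel peaks were narrow, with median widths of 345 bp for HA and 284 bp for YFP. Ear peaks were wider, with medians of 518 bp for HA and 649 bp for YFP, and they covered 4.08 and 10.3 Mb against 1.07 and 1.52 Mb in tassel. The median of the authors' score was 69.9 in tassel HA, 80.6 in tassel YFP, 57.9 in ear HA and 59.9 in ear YFP. A score of at least 100 was reached by 18.5% of tassel HA, 35.6% of tassel YFP, 4.07% of ear HA and 3.6% of ear YFP peaks. Most peaks rested on few fragments. The median summit height was 4 fragments in both tassel lists, 6 in ear HA and 8 in ear YFP, and 77.2% of tassel HA peaks and 59.2% of tassel YFP peaks had a height under 5. Paired by tag, the ear list held 2.31 times as many peaks as the tassel list with HA and 2.68 times as many with YFP, and its median width was 1.5 and 2.29 times that of tassel. With 2 such pairs an exact sign-flip test (two-sided) gave p = 0.5 for both measures, the smallest it can give, and list lengths depend on depth, so no difference between the tissues is called.

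The first comparison asks how far the 2 fusions, each with its own antibody, marked the same sites within a tissue. In tassel, 627 of 2875 HA peaks (21.8%, 95% interval 20.3 to 23.4) overlapped a YFP peak, whereas shifted HA peaks did so in 0.170% of cases, a 128-fold excess. In ear, 724 of 6641 HA peaks (10.9%, interval 10.2 to 11.7) overlapped a YFP peak against 0.911% by chance, a 12-fold excess, so that about 60.5 of the 724 are the number given by chance placement. Both excesses had a local-shift permutation p of 0.001, the smallest that the placements can give (adjusted p = 0.001 over 6 pairs). The share of either excess that comes from mappable or accessible sequence common to both libraries was not tested. Where tassel peaks overlapped, their summits lay a median of 5 bp apart (quartiles 2 and 38 bp, 627 pairs), against 116 bp for summits placed at random within the same peaks (permutation p = 0.001). In ear the median was 112.5 bp (quartiles 17 and 363 bp, 724 pairs) against 246 bp at random (permutation p = 0.001), but among peaks with a score of at least 100 it was 3 bp (75 pairs), close to the 5 bp of tassel (297 pairs). In a split made after seeing the data, ear pairs whose HA peak also overlapped a tassel peak had a median summit distance of 6 bp (217 pairs) against 157 bp at random, and those with no tassel peak 214 bp (507 pairs) against 303 bp at random (permutation p = 0.001 for both). The tassel share was 55.8% and the ear share 27.8% where only peaks with a score of at least 100 were compared. Among peaks with a summit height of at least 5, a selection chosen after seeing the data, they were 64.3% and 11.7%. That limit kept 655 of the 2875 tassel HA peaks but 5951 of the 6641 ear HA peaks. Heights are not scaled to depth, so these last 2 shares do not compare like with like. The tassel shares also count strong regions without an ear peak, described below, in which the 2 tags had nearly equal heights.

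Recovery with the other tag was highest in the highest score quartile of every list. In tassel HA, 52.4% of peaks in the highest score quartile had a YFP partner (interval 48.6 to 56.1), and 4.17% of the lowest quartile did (2.83 to 5.90). In tassel YFP these shares were 40.5% (37.7 to 43.3) and 1.17% (0.639 to 1.95). In ear the top quartile also stood above the rest, with 18.8% (16.9 to 20.8) against 7.89% (6.64 to 9.29) for HA and 9.38% (8.39 to 10.4) against 4.17% (3.51 to 4.92) for YFP. The intervals of the lower 3 score quartiles overlapped one another in both ear lists. They did not when peaks were ranked by summit height, where the lower 3 shares were 4.46%, 7.35% and 10.8% in ear HA and 2.52%, 4.08% and 5.73% in ear YFP. In ear, width rose with rank as well. From the lowest to the highest height quartile, median widths went from 461 to 653 bp in HA and from 493 to 955.5 bp in YFP. By score they went from 476 to 569.5 bp and from 563 to 820 bp. Wider peaks meet a partner more readily, and a chance share per quartile was not computed.

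**Figure D1:**
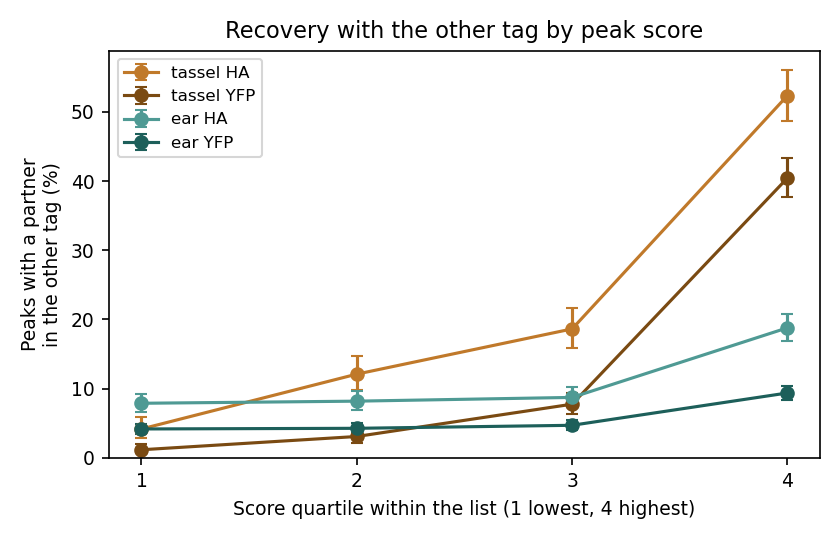
Share of peaks (%) that overlap a peak of the other tag in the same tissue, by score quartile of each list, with exact 95% binomial intervals as error bars. The tassel HA share runs from 4.17% in the lowest quartile to 52.4% in the highest, while in the ear lists the highest quartile stands apart.

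Merging the 4 lists gave 25032 regions, of which 23392 (93.4%) held peaks of 1 list only. Regions found with both tags numbered 621 in tassel and 721 in ear, and 140 were found in all 4 lists. The regions of all 4 lists with the highest scores were a neighbouring pair on chromosome 6. The first spans 140853414 to 140854419, with scores of 1703 in tassel HA, 3100 in tassel YFP, 3100 in ear HA and 2733 in ear YFP, and summit heights of 48, 123, 97 and 76 fragments in the same order. It also held the highest-scoring peak of both ear lists. The second spans 140855248 to 140855912, with summit heights of 53, 137, 112 and 108 fragments. The third, on chromosome 1 from 62371697 to 62372144, had heights of 51, 132, 109 and 98 fragments. The other regions of the 10 named lie on chromosome 5 from 2146108 to 2148277 and from 51156762 to 51157996, on chromosome 6 from 138679980 to 138681294, on chromosome 1 from 5639216 to 5639972 and from 290309008 to 290309616, on chromosome 7 from 135811773 to 135813095, and on chromosome 2 from 184008924 to 184010579. In each of the 10, the summit was higher with YFP than with HA in tassel, and higher with HA than with YFP in ear. All coordinates are AGPv2, and the genes around them were not analysed here. All 10 kept a score of at least 100 in every list.

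The second comparison asks which occupied regions tassel and ear have in common. Of the 621 regions found with both tags in tassel, 140 (22.5%, interval 19.3 to 26.0) were found with both tags in ear, 91 with 1 ear list, and 390 with neither. Of the 721 ear regions found with both tags, 80 were in 1 tassel list and 501 in neither. Shifted tassel regions met ear regions 0.431 times on average, against 140 observed (permutation p = 0.001), and over all merged regions the odds ratio between the statuses was 11.9 (Fisher's exact test, two-sided, p = 6.15e-85). Merged regions exist only where a list has a peak, and most hold peaks of 1 list only. The odds ratio and its p therefore depend on the number of such peaks and do not measure association over the genome. At a score of at least 100, 51 of the 75 ear regions left (68.0%) were also among the 296 tassel regions, of which they made up 17.2%. A region without a peak in a tissue did not pass the authors' threshold there, and a lower occupancy there was not separated from a lower depth.

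Tassel regions found with both tags and without an ear peak included the highest scores in the tassel lists. The 5 named are on chromosome 8 from 9420278 to 9420853 (summit heights 115 in HA and 110 in YFP) and from 134902740 to 134908848 (174 and 164), on chromosome 1 from 168908566 to 168909196 (162 and 169), on chromosome 4 from 156341289 to 156342426 (154 and 167) and on chromosome 5 from 54214503 to 54215067 (152 and 168). The highest tassel YFP score, 3135, was on chromosome 2 from 89810631 to 89811123, again without an ear peak. The YFP and HA heights were nearly equal in such regions. Among regions with summed tassel heights of at least 50, the mean log2 ratio of YFP to HA height was 0.05 ± 0.24 (SD, 58 regions) without an ear peak and 1.72 ± 0.73 (SD, 40 regions) with one, a difference of 1.67 (two-sided permutation test over regions, p = 1e-05, the smallest that 100000 permutations can give). The height threshold was chosen after seeing the data. The contrast was not limited to strong regions. Over all 390 tassel regions with both tags and no ear peak, median heights were 6 in HA and 8 in YFP. Over the 231 with an ear peak they were 6 and 20. The share of tassel regions with an ear peak was 10.1% at YFP heights of 5 to 9 fragments (199 regions), 71.7% at 20 to 39 (113 regions) and 31.2% at 80 or more (32 regions). By HA height it was 52% at 10 to 19 (75 regions), and none of the 20 regions at 80 or more had an ear peak, which allows a share of up to 15%.

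**Figure D2:**
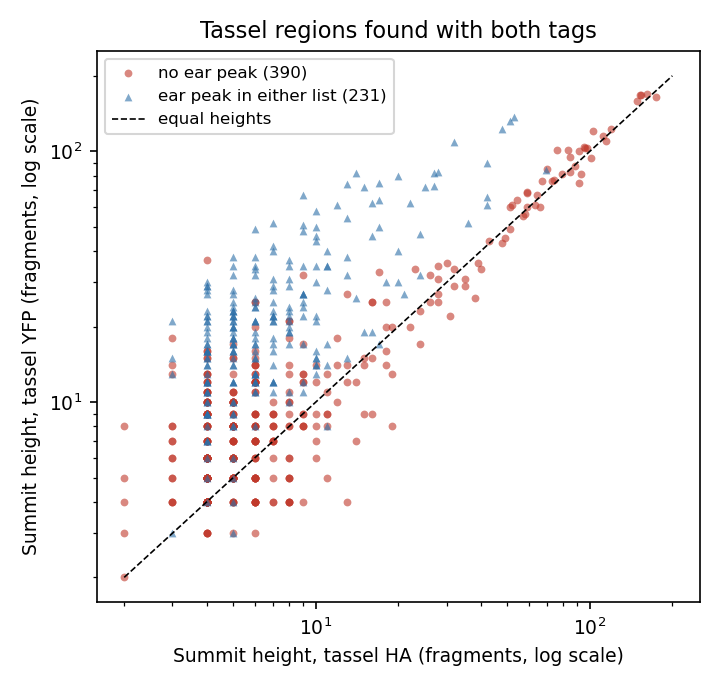
Summit heights (fragments, log scales) in tassel HA and tassel YFP for the 621 regions found with both tags, with 390 regions lacking an ear peak as circles, 231 with an ear peak as triangles, and a dashed line of equal heights. At high values the circles follow the line of equal heights and the triangles lie above it.

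Ear regions found with both tags and without a tassel peak were lower and wider than regions of all 4 lists. Their median summit heights were 7 fragments in HA and 9 in YFP, against 17 in both for regions of all 4 lists, and their median peak widths were 723 and 970 bp against 457 and 516 bp. The whole ear lists had median heights of 6 and 8 fragments and median widths of 518 and 649 bp. Against these lists the regions were not low, though they were wide. An overlap of 1 bp is enough to count, so wider peaks enter this set more readily. The 5 named are on chromosome 9 from 35404662 to 35407039, with scores of 120 in HA and 181 in YFP, on chromosome 5 from 31542019 to 31546022 (102 and 117), on chromosome 7 from 153677525 to 153678044 (125 and 97.1) and from 63305729 to 63308348 (88.8 and 96.1), and on chromosome 1 from 23231022 to 23232161 (95.8 and 104). At a score of at least 100 in both lists, 2 of these 5 were left.

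With lists limited to 2875 peaks each, the 6 pairs could be set side by side. Tassel HA and tassel YFP shared the most, 20.8% (interval 19.4 to 22.4). Tassel YFP and ear HA, which have neither tissue nor tag in common, came next with 13.7% (12.5 to 15.0). Among the top 100 peaks of each list this pair shared 40% (30.3 to 50.3) and ear HA and ear YFP 50% (39.8 to 60.2), intervals that overlap. In whole lists, the top 100 ear HA peaks had a tassel YFP partner in 98% of cases (92.96 to 99.8). They had an ear YFP partner in 88% (79.98 to 93.6), and these intervals overlap as well. The same ear HA peaks were looked up in both lists and no paired test was run, so the overlap does not show equal shares. Ear HA and ear YFP shared 7.20% (6.28 to 8.21), tassel HA and ear HA 7.17% (6.25 to 8.17), tassel YFP and ear YFP 6.54% (5.66 to 7.51), and tassel HA and ear YFP 4.63% (3.89 to 5.46). The highest chance share among shifted placements was 0.591%, and each pair had a permutation p of 0.001. Within a tag, full lists shared 8.42% of tassel HA peaks with ear HA (chance 0.328%) and 7.92% of tassel YFP peaks with ear YFP (chance 0.734%). Across tissue and tag, the full-list shares were 11% of tassel YFP peaks with ear HA (chance 0.308%) and 7.06% of tassel HA peaks with ear YFP (chance 0.774%). All 4 had a permutation p of 0.001. Among peaks with a score of at least 100 in both lists, ear HA held 16.9% of tassel HA and 11.4% of tassel YFP peaks, and ear YFP held 9.96% of tassel HA and 5.1% of tassel YFP peaks. The ear lists were then the shorter ones, and 33.3% of ear HA and 11.5% of ear YFP peaks lay in tassel HA, against 70.7% and 18.6% in tassel YFP.

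**Figure D3:**
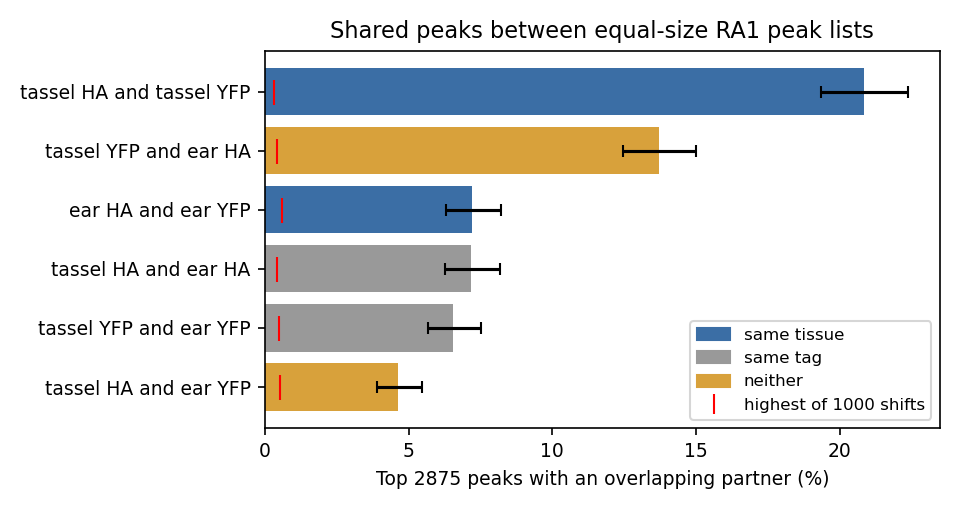
Share (%) of the 2875 highest-scoring peaks of each list that overlap those of the other, for all 6 pairs, with exact 95% binomial intervals, bars coloured by what the pair has in common and red ticks at the highest of 1000 shifted placements. Tassel HA and tassel YFP share 20.8%, tassel YFP and ear HA 13.7%, and the remaining 4 pairs lie between 4.63% and 7.20%.

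Tassel peaks lay toward chromosome ends more than an even spread gives. The outer 40% of the chromosome span held 47.1% of tassel HA peaks (45.2 to 48.9) and 48.2% of tassel YFP peaks (46.8 to 49.6). In ear they held 41.5% of HA peaks (40.3 to 42.7) and 41.4% of YFP peaks (40.5 to 42.2). At a score of at least 100 this contrast was lost, with overlapping intervals: the shares were 46.4% in tassel HA (42.1 to 50.8), 48.0% in tassel YFP (45.6 to 50.4), 48.5% in ear HA (42.4 to 54.7) and 44.8% in ear YFP (40.2 to 49.5). Of the regions found with both tags, 48.6% lay in the outer 40% in tassel (44.6 to 52.6) and 47.3% in ear (43.6 to 51.0), intervals that overlap. The middle 20% of the span held 16.6% and 16.4% of tassel peaks and 20.3% and 19.8% of ear peaks for HA and YFP. Between chromosomes, peak numbers lay between 0.852 times the number given by the span, on chromosome 3 in tassel YFP, and 1.14 times, on chromosome 2 in ear HA, and departed from it in tassel YFP (permutation p = 0.0002), ear HA (p = 0.0011) and ear YFP (p = 0.0001, the smallest the permutation draws can give) but not detectably in tassel HA (permutation p = 0.1551). Neighbouring peaks less than 10 kb apart were 2.56 times as frequent as under local shifts in tassel HA and 2.55 times in tassel YFP, against 1.55 in ear HA and 1.30 in ear YFP, each with a permutation p of 0.001.

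**Figure D4:**
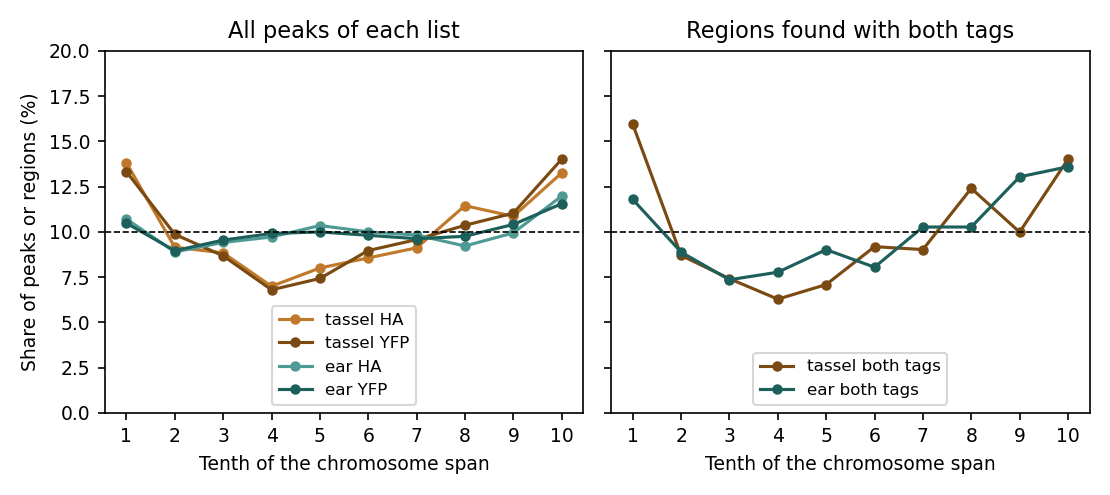
Share (%) of peaks in each decile of the chromosome span for the 4 lists (left) and for regions found with both tags (right), with a dashed line at the share of an even spread. The outer 40% of the span holds 47.1% and 48.2% of tassel HA and YFP peaks, 41.5% and 41.4% of ear HA and YFP peaks, and 48.6% and 47.3% of tassel and ear regions found with both tags.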

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

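The tests weighed below were chosen after the results were seen, and more explanations were tried than are weighed: a single ratio of YFP to HA height at all strong tassel regions was tested first, was argued against by a difference of 1.67 between regions with and without an ear peak, and gave its place to the ceiling.

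Agreement between the tags differed between the tassel and the ear libraries: at equal list lengths it was 20.8% in tassel and 7.20% in ear, a difference of 13.6 percentage points (Fisher's exact test over peaks, two-sided, p = 1.07e-51, which compares these libraries and not the tissues at large). With 1 library per tissue and tag, no difference between the tissues is called. Among the top 100 peaks of each list the intervals overlapped, at 69% in tassel (58.97 to 77.9) and 50% in ear (39.8 to 60.2). They were separate among the top 300, at 53% (47.2 to 58.8) and 23% (18.4 to 28.2), and the top 1000, at 35.4% (32.4 to 38.5) and 11.1% (9.22 to 13.2). Outside the 10 chromosomes, tassel YFP had 18 peaks on the mitochondrial and 8 on the plastid genome, with a median width of 1421 bp, while tassel HA had 1 organelle peak and the ear lists had none. On the unplaced sequence there were 37 peaks in tassel HA, 6 in tassel YFP, 7 in ear HA and 16 in ear YFP.

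The first pattern is that many of the strongest tassel regions had no ear peak: 10 of the 32 with a YFP height of 80 or more had one, and 0 of the 20 with such an HA height. A sensitivity lower by the same factor at every ear region would lose weaker tassel regions first, if tassel height followed occupancy throughout. Of those with YFP heights of 20 to 39, 71.7% (62.4 to 79.8) had an ear peak. At 80 or more, 31.2% (16.1 to 50.01) did, which is not the order that such a loss alone would give. The regions at 80 or more also state the pattern, so the comparison is not independent of it. A uniform loss joined with tassel reads that do not depend on the tag was not tested and stays open. The same holds for a loss of sensitivity at particular ear regions. A ceiling where both tags saturate, at the same height in every region, would leave regions below it with the unequal heights of other regions. Summed heights of 50 to 120, limits chosen after these heights had been seen, were used for this. The mean log2 ratio of YFP to HA height was then 0.026 ± 0.31 (SD, 27 regions) without an ear peak and 1.81 ± 0.73 (SD, 34 regions) with one. The 27 regions are among the 58 strong regions whose equal heights had already been seen, so this evidence is limited. A ceiling that differs between regions was not tested and stays open. A source of reads that does not depend on the tag also stays open. The heights of the 58 strong regions without an ear peak scattered around one ratio with a chi-square of 0.560 per degree of freedom, below the 95% limit of 1.33. That value lay below the lower 5% limit of 0.713 too, so the 2 tags agreed more closely than independent counts would. The test therefore does not decide for such a source. The 40 regions with an ear peak gave 3.82. No such source was identified: values of the input DNA were not analysed here, so that copy number and contamination stay open. Occupancy by RA1 in tassel alone stays open as well. It would need a ratio of YFP to HA height unlike that of strong regions with an ear peak (mean log2 of 0.05 in the 58 regions against 1.72 in the 40).

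The second pattern is that ear peaks found in 1 list only lay less toward the chromosome ends than those of tassel: the outer 40% of the span held 40.4% of such HA regions (39.1 to 41.7) and 40.9% of YFP regions (39.97 to 41.7) in ear, against 46.3% and 48.1% in tassel. Evenly placed background calls as the whole of these regions are argued against, since counts over the 10 deciles of the span departed from equal with a chi-square of 32.6 for ear HA (permutation p = 0.0002) and 39.3 for ear YFP (permutation p = 0.0001), from 8.84% and 9.02% in decile 2 to 11.6% and 11.4% in decile 10. A flat placement of every ear site is argued against by the 47.3% of ear regions with both tags in the outer 40% (43.6 to 51.0). Background that follows the mappable sequence, and a difference in the placement of weak sites between ear and tassel, were not tested and stay open.

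The third pattern is that the top 300 and top 2875 ear HA peaks shared more with those of tassel YFP, 45.0% and 13.7%, than with those of ear YFP, 23% and 7.20%, whereas over all 6641 ear HA peaks ear YFP held more partners, 724 against 520, and among the top 100 the intervals overlap. An exchange of the labels of the YFP libraries would make ear YFP the closer partner of tassel HA, yet those shared 4.63% of top peaks against 20.8% for tassel HA and tassel YFP. The order of scores in ear YFP alone was weighed with whole lists. Of the top 2875, 14.7% (13.5 to 16.1) had a partner anywhere in the ear YFP list. In the tassel YFP list 14.2% did (12.97 to 15.6). The ear YFP list is longer, with 12840 peaks over 10.3 Mb against 4797 over 1.52 Mb. It therefore meets more ear HA peaks by chance, also in the 724 against 520. The near tie thus does not decide whether that order accounts for the difference in the top 2875. It does not account for that in the top 300, where the shares were 50.7% (44.9 to 56.5) in ear YFP and 67.0% (61.4 to 72.3) in tassel YFP. A weaker signal in the ear YFP library stays open, on weak evidence, since the values were in view when it was proposed. Its mean share with the other 3 libraries was 6.12%, the lowest of the 4, against 9.36% for ear HA, 10.9% for tassel HA and 13.7% for tassel YFP. The mean of 6.12% includes the 7.20% shared with ear HA, which is itself part of the pattern. Whether antibody, sample, depth or a difference between the tissues lies behind it was not tested.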

How the results depend on the processing

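Of 187 alternative values, 150 moved by less than their interval, stayed on the same side of the threshold or, for counts, stayed within 1.5 times; 31 moved further, 5 lost and 1 gained significance, and none reversed. The inclusion of unplaced and organelle sequences, and the removal of summit heights under 5, of tassel heights of at least 40 and of strong tassel-only regions, were chosen after seeing the data. In 107 of 107 alternative overlap fits (the 6 pairs, the 6 equal-size pairs and the tissue overlap of both-tag regions) the overlap lay above chance, by 6.77 times or more, at a permutation p of 0.001. That is the smallest p the placements can give, so it says nothing of the sizes: shares of the shorter list ranged from 18.3% to 64.3% for tassel HA and YFP, from 5.23% to 27.8% for ear HA and YFP, and from 7.63% to 70.7% for tassel YFP and ear HA, where the shorter list changes with the score. The tissue overlap is given as a percent, a change made after its fold reached 25500 over a chance near 0. Pairing by replicate number was not possible because the groups share fewer than 2 such numbers. Pairing the tissues by tag was done, and gives 2 pairs and an exact sign-flip p of 0.5 at least. The alternatives for gene position, gene lists and motifs were not run. The share of tassel both-tag regions in the ear set, 22.5%, was 13% without the top 1% by score, 18.2% at a score of at least 70 and 17.2% at 100, while that of ear regions in the tassel set was 19.4%, and 11.6%, 54.5% and 68.0% in the same order. Peak numbers at scores of at least 70 and 100 were 1406 and 532 in tassel HA, 3064 and 1707 in tassel YFP, 1284 and 270 in ear HA, and 2986 and 462 in ear YFP. Regions with both tags at a score of at least 70 were 165 in ear and 90 in both tissues. At a score of at least 100 they were 296 in tassel, 75 in ear and 51 in both. With lists of equal length 207 were left in ear, and without the top 1% by score 75 in both tissues. Ranked by summit height, the share with a partner in the lowest quartile was 2.09% in tassel HA, 4.46% in ear HA and 2.52% in ear YFP, and in the highest quartile 63.8% in tassel HA and 21.0% in ear HA. Shares in the outer 40% of the span at a score of at least 100 were 48.5% in ear HA and 44.8% in ear YFP; among peaks with a partner in the other tag they were 49.1% in tassel HA, 47.4% in ear HA and 47.3% in ear YFP. Shares in the middle 20% at a score of at least 100 were 14.8% in tassel HA, 18.1% in ear HA and 18.0% in ear YFP, and 17.1% and 17% in ear HA and YFP peaks with a partner. The departure of chromosome counts from the span was lost at a score of at least 100 in ear HA (largest ratio 1.26, permutation p = 0.5528) and ear YFP (1.36, permutation p = 0.2822), and among peaks with a partner in tassel YFP (1.23, permutation p = 0.087), ear HA (1.27, permutation p = 0.4724) and ear YFP (1.25, permutation p = 0.5146), where fewer peaks were tested, and it was gained in tassel HA peaks with a partner (1.26, permutation p = 0.044). For the values that moved, other than where fewer peaks were kept, the cause was not tested. Median summit heights of 4 to 8 fragments limit how finely low-scoring peaks can be ranked.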

Other observations

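Some of the regions found in all 4 lists came in close pairs. Of the 140, 10 had another such region within 10 kb, against 0.402 on average and at most 4 under local shifts (permutation p = 0.001), and the 5 gaps between them measured 486 to 1256 bp with a median of 828 bp. The strongest pair is the one on chromosome 6 at 140853414 to 140854419 and 140855248 to 140855912. The pairs were noticed among the strongest regions first and tested on the same data, which hold those pairs. The p-value is therefore not independent evidence against chance placement, and the pairing remains a hypothesis.

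Regions of exactly 2 lists were unevenly divided among the combinations that cross tissues. Tassel YFP and ear HA alone shared 229 regions, tassel YFP and ear YFP 141, tassel HA and ear YFP 42, and tassel HA and ear HA 26. Chance placement gives 14.8, 35.2, 22.2 and 9.42 overlapping peaks for these pairs of whole lists, in the same order, so that much of the 42 is of the size of chance. The numbers are not corrected for list length, and at equal lengths tassel HA shared more with ear HA (7.17%) than with ear YFP (4.63%).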
